A study of Mus musculus with 6 samples.

How the data were processed

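Total RNA was measured in 3 stable 3T3 lines, each carrying a GFP-tagged HP1 protein under a doxycycline-inducible promoter. 3T3 is an established mouse embryonic fibroblast line. The HP1 proteins came from mouse (GFP-mHP1), fruit fly (GFP-dHP1) and fission yeast (GFP-Swi6). Each line gave 1 uninduced library and 1 library after 500 ng/ml doxycycline, and per the series' design text the induced cells were GFP-positive in cell sorting. Libraries were stranded and depleted of ribosomal RNA, per the labels' protocols.

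The deposited values are raw counts per gene or repeat element, which the authors made before deposit. Per the submitters' processing notes, STAR, DESeq2 and the mouse genome build GRCm39 were used. Their versions, the counting tool, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping genes on opposite strands are therefore uncertain, as are reads of near-identical gene copies and of repeat elements. The table held 36030 features, made up of 35782 genes with Ensembl identifiers and 248 repeat elements. Each had at least 2 counts in some library. Columns were matched to samples by name: the mark for control was read as the uninduced library, and the letter y as the yeast protein, Swi6. A reference annotation of build GRCm38 gave symbols for 33109 of the 35782 genes. It was used for names, gene classes and neighbours, and no coordinates are given because the builds differ. Transgene expression was not analysed here.

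Library totals ran from 38072250 to 44387081 counts. Features were kept by filterByExpr in edgeR with the line as group, a minimum count of 10, a minimum total of 15 and at least 2 libraries. This left 24449 features, 24260 genes and 189 repeat elements. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test with robust estimation (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment at 0.05. Induction was tested over all 6 libraries with the line as a block, since both libraries of a pair came from the same stable line. That fit had 2 residual degrees of freedom. The same fit gave an F test of the 3 lines and 3 pairwise contrasts. The response of 1 line against the mean of the other 2 was tested as an interaction with 1 residual degree of freedom, and leaving out a library or a line there would leave 0. Nothing in the labels says that the lines were made or grown as separate experiments, so p-values measure only the spread between these libraries.

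Each group was 1 library without replicates, so folds within a line have no test and no replicate check. They are ratios of CPM, the counts scaled by TMM to a common library total, with an exact Clopper-Pearson 95% interval, which covers counting error only. Genes with at least 50 counts over both libraries of a line were counted as higher or lower at 2-fold. A fold against 0 counts was taken against a floor of 3 counts in that library and is given with the exact lower bound. Log2 folds used for list medians and correlations carried a prior count of 2. Correlations across genes used genes with a mean CPM of at least 10, and genes are not independent replicates.

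The samples, designs, 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Restriction to protein-coding genes, edgeR without robust estimation, fits of the lines without 1 library and the removal of GFP-mHP1 markers or of a GFP-mHP1 share were added after the data were seen. The lists covered HP1 and H3K9 methylation machinery, zinc finger (Zfp) genes, imprinted genes, germline genes, interferon response, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, ATF4 targets, cell cycle, p53 targets, fibroblast extracellular matrix, contractile and YAP/SRF targets, immediate early genes, heat shock, endoplasmic reticulum stress, cholesterol synthesis, hypoxia and glycolysis, replication-dependent histones, NF-kB and inflammatory genes, ribosomal proteins and small nucleolar RNAs. Further lists covered markers of muscle, adipocytes, cartilage and bone, epithelium, leukocytes, endothelium, and neurons and glia, and abundant nuclear non-coding RNAs. Of 574 genes listed by name, 25 had no match among the counted features, and the expression filter removed further ones. Of 28 germline genes 19 were found and 10 tested, and of 15 leukocyte markers 13 were found and 7 tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1). Each list's median log2 fold was also ranked among 10000 random lists of the same size and expression.

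Named genes had a known symbol, not a predicted one, and in tests across lines a mean CPM of at least 5. For induction they were the genes past the threshold or, failing these, the 6 with the smallest p in each direction. For lines and responses they were the 5 highest and 5 lowest past the threshold, or the genes with the smallest p where none passed. For folds within a line they were the 6 highest and 6 lowest by the interval bound nearest to no change. List members were named by smallest p. 1 gene that this rule names within a line is not reported here.

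The scripts were tested on simulated counts for the 24449 features, with 200 changed by known folds. At 2-fold, 4-fold and 8-fold the induction test recovered 32%, 100% and 100% of changed genes, and the test of the lines 28%, 100% and 100%. The response test recovered 0%, 22% and 62% for GFP-mHP1, 0%, 36% and 62% for GFP-dHP1, and 14%, 74% and 98% for GFP-Swi6. The counts were drawn from fitted means and dispersions, without further differences between the lines in their response. In the real counts P2rx7 had log2 folds of 1.91, 2.25 and 2.64 in the GFP-mHP1, GFP-dHP1 and GFP-Swi6 lines. Its edgeR adjusted p for induction was 0.804, so the shares recovered may be too high for the real data. Alternatives were DESeq2 1.42.0, limma-voom, other normalizations, gene filters and count minimums, models without the block, and fits without 1 line or 1 library.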

Results

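RNA was compared between uninduced and doxycycline-induced cells of 3 mouse fibroblast lines that carry HP1 from mouse, fruit fly or fission yeast. HP1 proteins bind methylated histone H3 lysine 9 in heterochromatin. The series asks how HP1 homologs from different species affect gene expression. The 6 libraries held 44387081 (GFP-mHP1 uninduced), 40897124 (GFP-mHP1 induced), 40104620 (GFP-dHP1 uninduced), 38072250 (GFP-dHP1 induced), 40588213 (GFP-Swi6 uninduced) and 41230964 (GFP-Swi6 induced) counts. Across 10176 genes, both GFP-dHP1 libraries correlated at r = 0.988, the GFP-mHP1 pair at 0.954 and the GFP-Swi6 pair at 0.874. The uninduced libraries of the GFP-mHP1 and GFP-dHP1 lines correlated at 0.708, and those of the GFP-mHP1 and GFP-Swi6 lines at 0.918. The abundant nuclear RNA Malat1 took 0.445%, 0.793%, 1.98%, 2.28%, 0.910% and 2.29% of counts in the 6 libraries, in the order given for the totals.

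The mouse HP1 genes were read first in every library. Cbx5, which encodes HP1 alpha, stood at 759 CPM before and 960 CPM after induction in the GFP-mHP1 line, at 487 and 470 CPM in the GFP-dHP1 line, and at 845 and 485 CPM in the GFP-Swi6 line. Cbx1, which encodes HP1 beta, stood at 90.0 and 74.2, 41.8 and 35.3, and 70.7 and 41.1 CPM in the same order. Cbx3, which encodes HP1 gamma, stood at 131 and 129, 123 and 127, and 157 and 105 CPM. None of these genes passed edgeR's test of induction over the 3 lines, with adjusted p-values of 0.907 (Cbx5), 0.804 (Cbx1) and 0.868 (Cbx3). Without the GFP-Swi6 line the log2 changes of Cbx5 and Cbx3 had the opposite sign, at 0.15 and 0.015. Which mouse HP1 the GFP-mHP1 line carries is not given in the sources used here. Counts of the matching gene in that line may include reads of the transgene, which were not told apart from endogenous RNA.

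The first comparison asked which genes moved alike with induction in all 3 lines. The gene with the smallest p was P2rx7 (ENSMUSG00000029468), an ATP-gated ion channel, at 1.85 and 7.07 CPM before and after induction in the GFP-mHP1 line, 6.16 and 29.4 CPM in the GFP-dHP1 line and 4.77 and 30.0 CPM in the GFP-Swi6 line. Its log2 change was 2.29 (SE 0.24), in the same direction in 3 of 3 lines. The metallothioneins Mt1 and Mt2, which bind metals, had log2 values of 1.19 (SE 0.23) and 1.88 (SE 0.29), but Mt2 is overlapped over 73.5% of its length by an antisense gene, Gm45774, with nearly equal CPM in every library. Tnfrsf1b, a TNF receptor, had 0.96, Mfap5, a microfibril protein, 1.02, and Pla2r1, a phospholipase receptor, 3.58, which rests on the GFP-Swi6 line (2.36 and 41.6 CPM), with at most 0.174 CPM in the other lines. On the lower side were the ephrin ligand Efnb1 at -1.43 (SE 0.20), the nuclear protein gene Banp at -1.18 (SE 0.17), Dlk2 at -1.14, Igsf9 at -1.55, Chtf8 at -0.82, whose reads are uncertain because another gene model of the same name overlaps 100% of it on the same strand, and the linker histone gene Hist1h1e at -1.05, which shares 25.7% of its length with Hist1h2be. None of these passed, each with an edgeR adjusted p of 0.804. edgeR called 0 of 24449 features, with 1354 at an unadjusted p below 0.05. limma-voom called 0, and DESeq2 called 37, among them P2rx7 (adjusted p = 4.27e-11), Efnb1 (4.72e-05) and Mt2 (6.79e-05). Leaving out the GFP-dHP1 line gave 68 features by edgeR, P2rx7 (adjusted p = 0.0479), Pla2r1 (0.0153) and Igsf9 (0.0400) among them.

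The folds within each line were largest in number in the GFP-Swi6 line, where 2289 of 18983 genes were at least 2-fold higher and 1734 at least 2-fold lower in the induced library. In the GFP-mHP1 line 875 of 18268 genes were higher and 331 lower. In the GFP-dHP1 line 280 of 19167 genes were higher and 175 lower, so that 61.5% of the changed genes were higher. With library size as the only scaling that share was 75.4%, out of 512 genes, and at a minimum of 200 counts it was 40%, out of 110 genes, so that most were lower. These counts depend on the minimum count, and at 200 counts they were 552, 110 and 2497 genes in the GFP-mHP1, GFP-dHP1 and GFP-Swi6 lines.

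**Figure D1:**
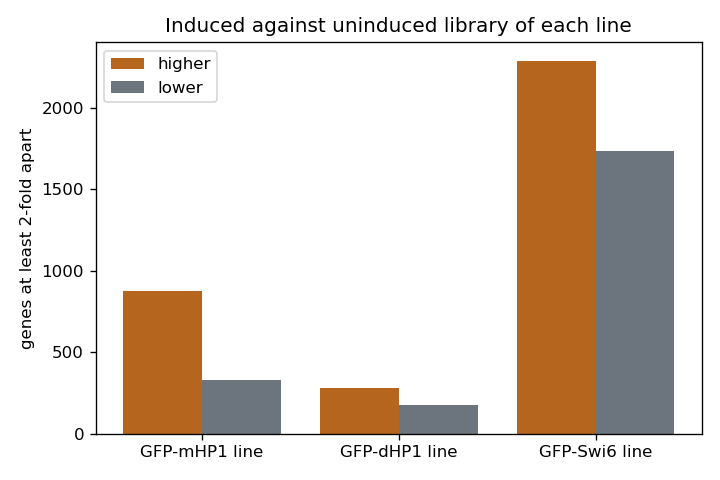
Number of genes at least 2-fold higher or lower in the induced than in the uninduced library of each line, among genes with at least 50 counts over both libraries. The bars reach 2289 and 1734 genes in the GFP-Swi6 line, 875 and 331 in the GFP-mHP1 line and 280 and 175 in the GFP-dHP1 line.

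After induction of GFP-mHP1, 4 of the 6 genes named as highest, Ifi44, Oas2, Mx2 and Oasl2, were on the interferon response list. Ifi44 was 46.6-fold higher (interval 37.8 to 58.1), Oas2, a double-stranded RNA sensor, 43.1-fold (24.5 to 84.0), the antiviral GTPase gene Mx2 36.3-fold (27.2 to 49.6), Slfn8 30.8-fold (23.1 to 42.0) and Oasl2 27.6-fold (23.3 to 33.0). Tmprss2, a membrane serine protease, had 0 counts before and 105 after induction, at least 28.7-fold higher by the exact interval, with a value of 35.9-fold against the floor of 3 counts. Lower were Selp, the adhesion molecule P-selectin, at 0.151 of its uninduced level (0.103 to 0.215), Ccdc184 at 0.185, Gpr149 at 0.264, Galnt18 at 0.285, the transcription factor gene Atoh8 at 0.295 and the histone gene Hist1h2bq at 0.309.

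After induction of GFP-dHP1 the folds of the genes named as higher were smaller than in the GFP-mHP1 line. The non-coding RNA Bc1 was 6.06-fold higher (4.24 to 8.87), P2rx7 4.78-fold (4.17 to 5.49), the lectin gene Cd209c 5.82-fold (3.94 to 8.88), Tmeff2 5.92-fold (3.19 to 11.98), and the multicopy genes Usp17lb and Zscan4e 5.63-fold (4.13 to 7.82) and 8.22-fold (3.52 to 23.5). Reads of the multicopy genes are uncertain because near-identical copies share them. Lower were Csrnp3 at 0.0759 of its uninduced level (0.0270 to 0.173), Sgsm1 at 0.149, U90926 at 0.186, the syntaxin-binding gene Stxbp2 at 0.249 and Cyp26b1, which degrades retinoic acid, at 0.281. Csrnp3, Stxbp2 and U90926 were also among the genes that set the GFP-mHP1 line apart from the others, and stood at 1.89, 43.5 and 2.96 CPM in the GFP-dHP1 uninduced library against 110, 535 and 29.3 CPM in the GFP-mHP1 uninduced library.

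After induction of GFP-Swi6 the growth factor gene Igf2 (ENSMUSG00000048583) was 162-fold higher (136 to 195) and Dio2, which activates thyroid hormone, 112-fold (80.9 to 160). The complement gene C4b was 60.2-fold higher (46.0 to 80.3), the serpin gene Serpina3n 53.3-fold (41.6 to 69.4) and Islr 45.9-fold (35.7 to 60.2). Oas1e went from 1 to 375 counts, a ratio of 360 with an interval of 64.2 to 14250, and has close paralogs. Lower were the LIM-domain gene Fhl1 at 0.0951 of its uninduced level (0.0785 to 0.114), the neurotrophin receptor gene Ntrk3 at 0.122, the PCNA-binding factor gene Pclaf at 0.138 and the histone genes Hist1h2ap, Hist1h2bk and Hist1h3b at 0.139, 0.143 and 0.149.

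Among the gene lists, the interferon response stood out in the GFP-mHP1 and GFP-Swi6 lines. Of its 36 members, 31 were at least 2-fold higher after induction in the GFP-mHP1 line (median log2 fold 2.97) and 29 in the GFP-Swi6 line (1.75). In the GFP-dHP1 line 0 were (median -0.16), and its uninduced library already held these genes at a median of 116 CPM, against 3.61 CPM in the GFP-mHP1 and 3.42 CPM in the GFP-Swi6 uninduced libraries. The antiviral gene Rsad2 was at 1.24 and 22.8 CPM before and after induction of GFP-mHP1, at 36.1 and 50.1 CPM with GFP-dHP1 and at 3.27 and 21.2 CPM with GFP-Swi6. Xaf1 was at 2.43 and 34.0, 83.0 and 87.4, and 2.18 and 24.96 CPM, and the chemokine gene Cxcl10 at 6.61 and 41.3, 45.6 and 53.3, and 4.99 and 22.6 CPM. Over the 3 lines camera called the list higher (adjusted p = 1.76e-28), and the adjusted p was 0.607 with an estimated correlation. By edgeR 0 members passed for induction, over all genes or adjusted over the list alone, and 18 had an unadjusted p below 0.05. The response of the GFP-dHP1 line was lower than that of the others in 27 members adjusted over the list alone and in 0 over all genes.

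Cell cycle and histone genes were lower in the GFP-Swi6 induced library. Of 37 cell cycle genes, 34 were at least 2-fold lower there (median log2 fold -1.64), against 0 in the GFP-mHP1 line (-0.28) and 0 in the GFP-dHP1 line (0.13). The ribonucleotide reductase gene Rrm2 was at 71.6 and 17.9 CPM before and after induction of GFP-Swi6, the licensing factor gene Cdc6 at 45.5 and 9.27 CPM, the replication clamp gene Pcna at 198 and 86.2 CPM and E2f1 at 43.2 and 19.9 CPM. The GFP-dHP1 line held the list at a median of 23.8 and 27.2 CPM, below 120 and 100 CPM in the GFP-mHP1 line. Of 61 replication-dependent histone genes, 54 were at least 2-fold lower after induction of GFP-Swi6 (median log2 fold -2.17) and 29 after induction of GFP-mHP1 (-0.99). The GFP-dHP1 median for the histones was -0.07, with the opposite sign when scaled by library size alone. camera called both lists lower over the 3 lines, with adjusted p-values of 2.97e-14 for cell cycle and 1.59e-42 for histones. The adjusted p was 0.609 with an estimated correlation for cell cycle and 0.607 for histones. Without the GFP-Swi6 line the cell cycle list did not pass camera (adjusted p = 0.169). In the test of the GFP-Swi6 response against the other lines, edgeR found 20 cell cycle genes lower over all genes and 34 adjusted over the list alone. For histones it found 12 lower over all genes, and 51 lower and 1 higher adjusted over the list alone.

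**Figure D2:**
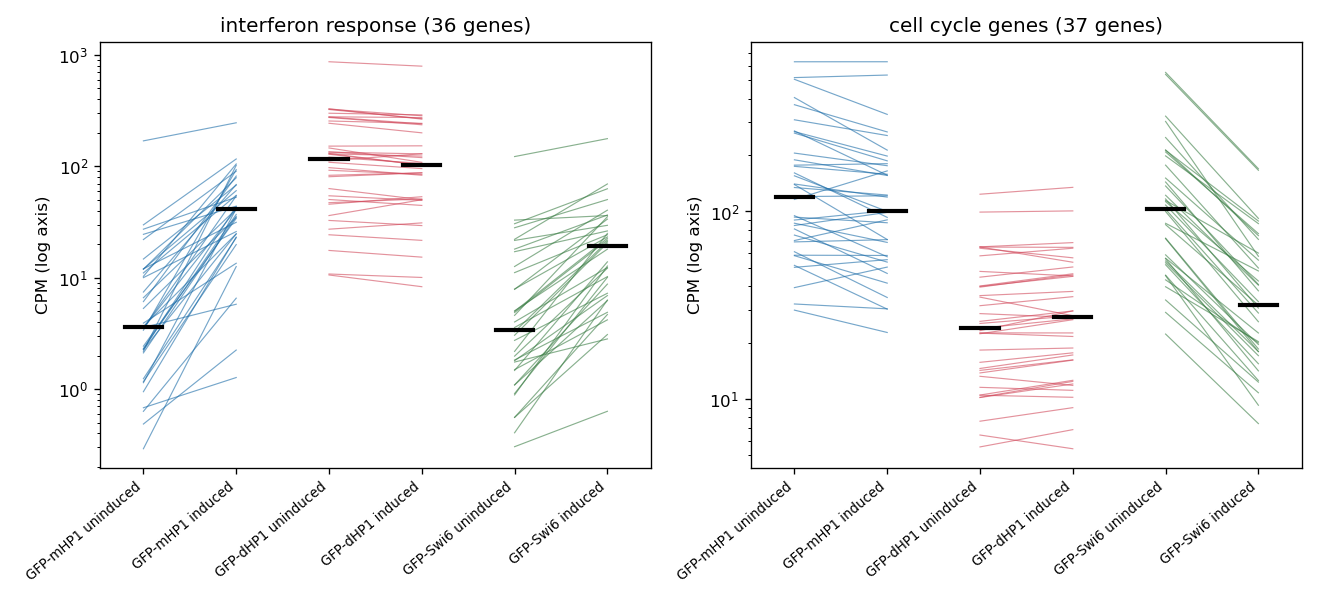
CPM on a log axis of the 36 interferon response genes and the 37 cell cycle genes in the 6 libraries, with 1 line per gene from the uninduced to the induced library and black bars at the medians. The interferon medians were 3.61 and 41.2 CPM in the GFP-mHP1 line, 116 and 102 CPM in the GFP-dHP1 line and 3.42 and 19.3 CPM in the GFP-Swi6 line, and the cell cycle medians of the GFP-Swi6 line were 103 and 31.7 CPM.

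Several other lists differed between the lines in their medians. The GFP-mHP1 response of these lists was set against the other lines by camera, a test added after the data were seen. At the preset correlation it called NF-kB (adjusted p = 7.25e-09) and cholesterol synthesis genes (1.11e-05) higher. With an estimated correlation it called none of these lists (0.764 to 0.995). NF-kB and inflammatory genes were higher in the GFP-mHP1 line (median log2 fold 1.04, 13 of 22 at least 2-fold higher), with medians of -0.24 in the GFP-dHP1 and 0.20 in the GFP-Swi6 line. The chemokine gene Ccl2 was at 124 and 386 CPM in the GFP-mHP1 line and the acute-phase gene Saa3 at 57.9 and 975 CPM in the GFP-Swi6 line. camera called this list higher (adjusted p = 0.00235), with an adjusted p of 0.661 with an estimated correlation, and did not without the GFP-mHP1 line (0.667). Cholesterol synthesis genes had medians of 0.59, 0.34 and -0.68 in the GFP-mHP1, GFP-dHP1 and GFP-Swi6 lines. Their GFP-Swi6 response was lower in 5 of 22 genes over all genes and in 18 adjusted over the list alone. The list itself did not pass (camera adjusted p = 0.595). Imprinted genes had medians of 0.02, -0.31 and 0.61, with 10 of 25 at least 2-fold higher in the GFP-Swi6 line, and immediate early genes medians of -0.03, -0.19 and 0.74, with 8 of 22 higher there. The GFP-mHP1 sign of the immediate early genes turned with library size scaling. Extracellular matrix genes had medians of -0.05, -0.27 and 0.42, again with a GFP-mHP1 sign that turned. These lists did not pass over the 3 lines (camera adjusted p = 0.595, 0.630 and 0.556). Without the GFP-dHP1 line they passed (0.00551, 0.0380 and 0.00124), and cholesterol synthesis passed without the GFP-Swi6 line (5.57e-10). In the GFP-Swi6 response, imprinted genes had 3 higher over all genes, and 10 higher and 1 lower adjusted over the list alone. Immediate early genes had 3 and 6 higher, and extracellular matrix genes 2 and 3.

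**Figure D3:**
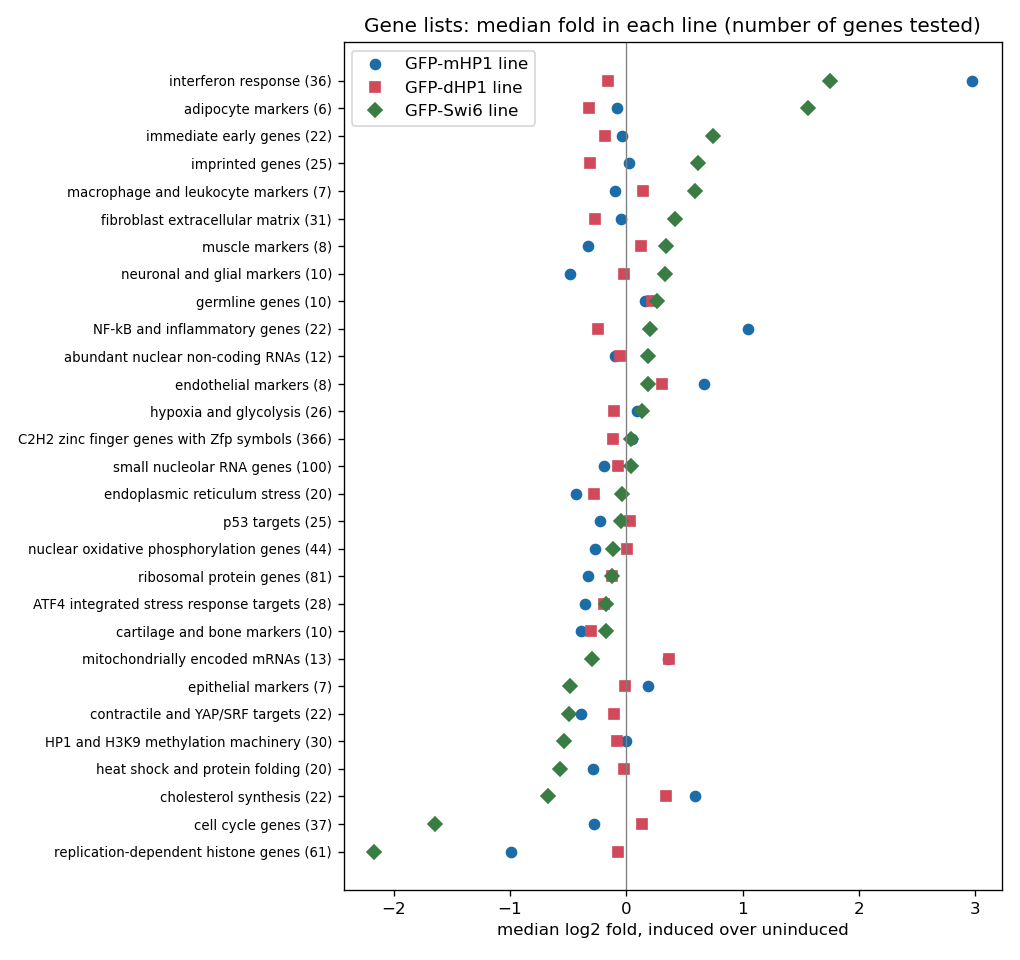
Median log2 fold, induced over uninduced, of the 29 gene lists in each line, with the number of tested genes in parentheses. Interferon response reaches 2.97 in the GFP-mHP1 line and histones -2.17 in the GFP-Swi6 line, while the medians of the GFP-dHP1 line lie between -0.32 (adipocyte markers) and 0.36 (mitochondrially encoded mRNAs).

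The other lists that camera called had smaller medians. HP1 and H3K9 methylation machinery was lower (adjusted p = 0.000551, and 0.609 with an estimated correlation), with a median of -0.54 and 8 of 30 genes at least 2-fold lower in the GFP-Swi6 line. Its member Uhrf1, which reads methylated DNA, was at 316 and 54.5 CPM there and had a lower response than in the other lines (log2 -2.09, edgeR adjusted p = 0.0363). The GFP-mHP1 and GFP-dHP1 medians of that list, -0.00 and -0.08, changed sign with library size scaling. Cell cycle genes were lower in the GFP-Swi6 line too (median log2 fold -1.64). A link between their fall and that of the HP1 machinery was not tested. Ribosomal protein genes (adjusted p = 4.81e-05), heat shock genes (0.000213), ATF4 targets (0.00215) and contractile and YAP/SRF targets (0.00227) were called lower, each with an adjusted p of 0.607 with an estimated correlation. Their GFP-mHP1 medians were -0.33, -0.28, -0.35 and -0.39, and their GFP-Swi6 medians -0.12, -0.57, -0.17 and -0.49. Among random lists of the same size and expression, these GFP-Swi6 medians ranked at percentiles 71.1, 0.15, 34.3 and 0.65. Those of ribosomal protein genes and ATF4 targets were thus not low for their expression in that line. Endoplasmic reticulum stress genes were called lower (0.00150, and 0.609 with an estimated correlation), with Calr at 1385 and 849 CPM in the GFP-mHP1 line, and nuclear oxidative phosphorylation genes were called lower (0.00214, and 0.661 with an estimated correlation). Mitochondrially encoded mRNAs were called higher (0.0167, and 0.609 with an estimated correlation), with medians of 0.36, 0.36 and -0.30. Endothelial markers were called higher (0.0229, and 0.607 with an estimated correlation), all low, with a median of at most 0.722 CPM. 2 of their 8 genes, Vwf and Tek, passed for induction adjusted over the list alone and 0 over all genes. Without the GFP-mHP1 line camera no longer called mitochondrially encoded mRNAs (0.525), oxidative phosphorylation (0.148), ATF4 targets (0.0702), contractile targets (0.127), endoplasmic reticulum stress (0.148), ribosomal proteins (0.0845) or endothelial markers (0.129). Without the GFP-dHP1 line mitochondrially encoded mRNAs (0.158) and endoplasmic reticulum stress (0.0762) were lost, and without the GFP-Swi6 line the HP1 machinery (0.302). In all 13 lists passed with the preset correlation, and 0 with an estimated correlation or by fry.

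The remaining lists did not pass by camera. Adjusted p-values were 0.595 for zinc finger genes, 0.0785 for germline genes, 0.803 for p53 targets, 0.556 for hypoxia and glycolysis and for nuclear non-coding RNAs, and 0.0527 for small nucleolar RNAs, which passed without the GFP-Swi6 line (0.000674) and with a stricter gene filter (0.0312). For markers of other cell types they were 0.963 for muscle, 0.895 for adipocytes, 0.145 for cartilage and bone, 0.963 for epithelium, 0.299 for leukocytes and 0.595 for neurons and glia. The leukocyte markers had medians of 2.14 and 1.99 CPM before and after induction in the GFP-mHP1 line, 5.68 and 6.89 CPM in the GFP-dHP1 line and 2.33 and 3.77 CPM in the GFP-Swi6 line. The count of genes passing for induction, adjusted over the list alone, was 1 each for imprinted genes and nuclear non-coding RNAs, in both cases Meg3, and 0 over all genes. Meg3 had 0 counts in the 4 libraries of the GFP-mHP1 and GFP-dHP1 lines, so its result rests on the GFP-Swi6 pair alone.

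The induction effect of each line was set against the mean of the others. That of GFP-Swi6 differed in 798 features by edgeR, with 503 higher and 295 lower. The spread in each of these tests comes from the difference between the remaining lines, so that the GFP-Swi6 change widens it in the tests of GFP-mHP1 and GFP-dHP1, and their counts do not rank the lines. The highest were Igf2 at 7.30 on the log2 scale (adjusted p = 0.0446), Dio2 at 6.75 (0.0260), C4b at 6.24 (0.01001), the cytochrome gene Cyp2d22 at 5.41 (0.0187) and Spats2l at 5.40 (0.01001). Igf2 stood at 3.14 and 508 CPM in the GFP-Swi6 line, 115 and 79.0 CPM in the GFP-dHP1 line and 0.437 and 1.12 CPM in the GFP-mHP1 line. Spats2l stood at 0.760 and 28.7, 17.9 and 17.0, and 6.83 and 5.65 CPM in the same lines. The lowest were the netrin receptor gene Unc5c at -3.25 (0.0156), the calcitonin receptor-like gene Calcrl at -2.86 (0.0156), the DNA glycosylase gene Neil3 at -2.76 (0.0228), the ankyrin gene Ank1 at -2.73 (0.0187) and the splicing regulator gene Mbnl3 at -2.73 (0.0193). Igf2 overlaps Gm49394 over 62.8% of its length, and its call was lost without a gene filter (adjusted p = 0.112), with a stricter one (0.0503) or among protein-coding genes (0.0768), against 0.0446 as tested. Without a gene filter edgeR called 3126 features.

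For the GFP-dHP1 line edgeR called 0 features, with 566 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0726. That value belonged to Oas2 (log2 -5.10), C4b (-6.16) and Iigp1, an interferon-inducible GTPase (-4.78), which were lower in their response than in the other lines. Gpr149 (1.91), Hist1h2bq (1.69) and Hist1h3e (1.89) led the higher side, with adjusted p-values of 1. DESeq2 called 65 features, all lower, limma-voom 0, and edgeR with RLE normalization 20. Oas2, C4b and Iigp1 passed with DESeq2, and by edgeR with RLE normalization, without a gene filter and among protein-coding genes. For the GFP-mHP1 line edgeR called 0, with 315 at an unadjusted p below 0.05, DESeq2 7 and limma-voom 0. Trim30d (log2 3.48), the interleukin receptor antagonist gene Il1rn (3.86) and Parp14 (3.19) led the higher side and Dio2 (-7.05), Smoc1 (-4.58) and Lgr6 (-2.39) the lower, each with an edgeR adjusted p of 1. Trim30d, Il1rn and Parp14 passed with DESeq2 and by edgeR without a gene filter, and Dio2 only by the latter.

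Across 10176 genes the log2 folds of the GFP-Swi6 and GFP-mHP1 lines correlated at r = 0.338 (rho = 0.226), those of the GFP-dHP1 and GFP-mHP1 lines at 0.168 (0.218) and those of the GFP-Swi6 and GFP-dHP1 lines at -0.0991 (-0.102). No library enters more than 1 line's fold. With genes of a mean CPM of at least 1 the first of these was 0.214, and with a share of the GFP-mHP1 induced library subtracted from the GFP-dHP1 uninduced library, an alternative chosen after seeing the data, the last was -0.225.

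Repeat elements were read as a group, as HP1 acts at repeats in heterochromatin. The endogenous retroviral elements MMVL30-int and RLTR4_MM-int went from 11.5 to 286 CPM and from 24.9 to 262 CPM in the GFP-Swi6 line, 24.9-fold (22.7 to 27.4) and 10.5-fold (9.85 to 11.2). In the GFP-dHP1 line they stood at 6.01 and 6.39 CPM and at 14.9 and 15.5 CPM. Their GFP-Swi6 response differed from that of the other lines (log2 4.16 and 2.99, edgeR adjusted p = 0.0143 and 0.0217), as did that of RLTR6_Mm (4.87, 0.0365), MMERVK10D3_I (3.62, 0.0228) and the B2-family element B3 (2.22, 0.0445). Summed over 189 repeat elements, levels went from 291 to 887 CPM in the GFP-Swi6 line, from 182 to 285 CPM in the GFP-mHP1 line and from 701 to 825 CPM in the GFP-dHP1 line. Without MMVL30-int and RLTR4_MM-int, a sum taken after their values were seen, the GFP-Swi6 levels were 255 and 339 CPM. The GFP-mHP1 levels were then 168 and 261 CPM and the GFP-dHP1 levels 680 and 803 CPM. Against the full sums, both elements together were thus higher after induction in the GFP-mHP1 line too. The 58 L1 elements summed to 110 and 88.6 CPM in the GFP-Swi6 line, lower after induction, and to 63.98 and 114 CPM in the GFP-mHP1 line and 235 and 307 CPM in the GFP-dHP1 line. The share of counts in the nuclear RNA Malat1 was also higher in each induced library, at 0.910% and 2.29% before and after induction in the GFP-Swi6 line, 0.445% and 0.793% in the GFP-mHP1 line and 1.98% and 2.28% in the GFP-dHP1 line. The share of counts in protein-coding genes was 92.1% and 89.3%, 91.8% and 92.7%, and 89.9% and 89.8% in the same order. No repeat passed for induction over the 3 lines by edgeR, with 15 at an unadjusted p below 0.05. As a group the 189 repeats were called higher by camera (adjusted p = 8.67e-12), with an adjusted p of 0.281 with an estimated correlation. The 7 families tested were called higher too, with adjusted p-values from 4.77e-06 (L1) to 0.00364 (ERVL), and from 0.281 to 0.299 with an estimated correlation.

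**Figure D4:**
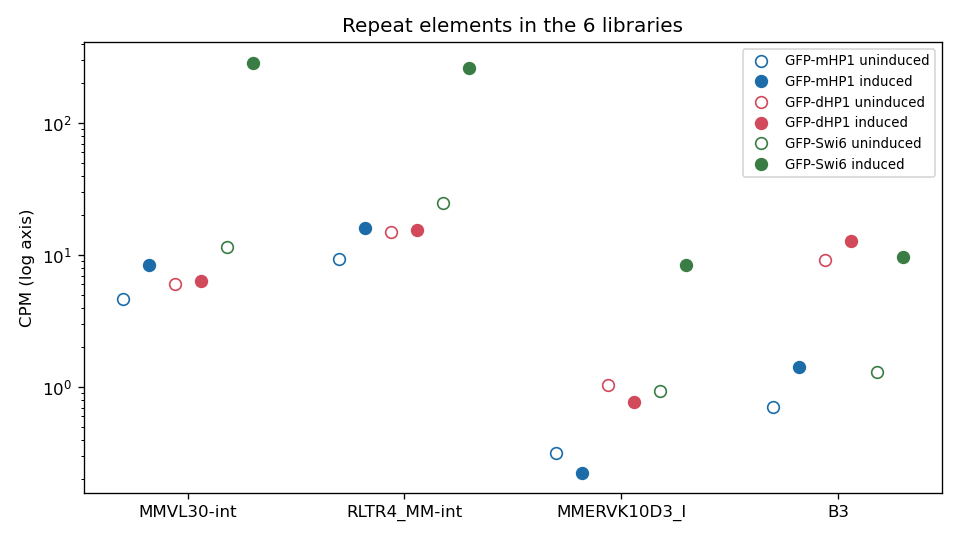
CPM on a log axis of 4 repeat elements in the 6 libraries, open for uninduced and filled for induced. MMVL30-int reaches 286 CPM and RLTR4_MM-int 262 CPM in the GFP-Swi6 induced library, while B3 is at 9.22 and 12.9 CPM in the GFP-dHP1 line.

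The 3 lines also differed from each other in the test that held induction in the model. The line and the HP1 homolog it carries cannot be told apart there. The GFP-dHP1 line held high levels of Apod, a lipid carrier of the lipocalin family (217 and 125 CPM, against at most 1.14 CPM in the other libraries), Fmod, the matrix proteoglycan fibromodulin (376 and 173 CPM), the protease gene Pappa2 (301 and 202 CPM), the carboxylesterase gene Ces1d (59.1 and 28.6 CPM) and the angiotensin receptor gene Agtr2 (38.2 and 18.9 CPM). Their edgeR F tests had adjusted p-values of 0.0114, 0.00301, 0.00520, 0.00379 and 0.00382. It held low levels of Mmp10, Ror2, Acot1, Rgs16 and Eps8l2, with log2 differences from the mean of the others of -5.83, -5.56, -5.11, -5.03 and -4.92. The F test's call of Ror2 was lost without a gene filter (edgeR adjusted p = 0.137), with a stricter one (0.0562) and among protein-coding genes (0.0507), and that of Apod without a filter (0.0565). In the GFP-mHP1 line Stxbp2 (535 and 726 CPM) and Trappc5, a vesicle-tethering subunit (609 and 599 CPM), were high (adjusted p = 0.0104 and 0.00382), as were Csrnp3 (0.0177), Fcor (0.0115) and U90926 (0.0202). Ephb6, Prkd1, Ms4a4d, Mmp16 and C4b were low in it, with at most 0.0996 CPM. In the GFP-Swi6 line the Y-linked helicase gene Ddx3y (18.2 and 20.3 CPM), the imprinted genes Grb10 (15.995 and 150.1 CPM) and Meg3 (2.86 and 105.7 CPM), Pi15 (9.18 and 35.8 CPM) and Cd55 (8.67 and 30.1 CPM) were high. Csmd3, Oas1g, Csrnp3, Sorcs1 and Iigp1 were low against the mean of the other lines. Csrnp3 (0 and 0.292 CPM) was also low in the GFP-dHP1 line (1.89 and 0.144 CPM). Sorcs1 (0 and 0 CPM) was also low in the GFP-mHP1 line (0.194 and 0.498 CPM). Iigp1 was at 0.0253 and 1.48 CPM, against 0.389 and 7.97 CPM in the GFP-mHP1 line. Ddx3y, Pi15 and Meg3 had 0 counts in the other 4 libraries. Their edgeR adjusted p-values were 0.00736, 0.00731 and 0.00554, and DESeq2's 0.157, 0.162 and 0.180. DESeq2 did not call Cd55 either (0.0869), and Meg3 was lost with induction left out of the model (0.0522).

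The F test of the lines called 3389 of 24449 features, 73 of them repeats. Between GFP-dHP1 and GFP-mHP1 4578 features differed, 2231 higher and 2347 lower in GFP-dHP1, and the 84 repeats among them were all higher in GFP-dHP1. Between GFP-Swi6 and GFP-dHP1 1681 differed (821 higher and 860 lower in GFP-Swi6), with all 43 repeats lower in GFP-Swi6, and between GFP-Swi6 and GFP-mHP1 158 (99 and 59). The last count was 1343 with DESeq2, 563 without a gene filter and 42 with a stricter one. For GFP-Swi6 against GFP-dHP1 DESeq2 called 3513 features (1862 higher and 1651 lower), limma-voom 1695 (890 and 805) and edgeR with a stricter filter 764 (386 and 378), so that the larger side turned. For GFP-dHP1 against GFP-mHP1 the larger side turned without a gene filter (2582 higher and 2380 lower). Without the GFP-Swi6 line that contrast gave 10364 features, and without the GFP-dHP1 line GFP-Swi6 against GFP-mHP1 gave 587. The spread in this fit is how far the lines differ in their response to induction. The GFP-Swi6 change widens it, so these counts do not rank the differences between the lines. Of the lists, 26 of 36 interferon genes, 18 of 37 cell cycle genes and 34 of 61 histone genes passed the F test. In the GFP-dHP1 line, 31 cell cycle and 57 histone genes were lower and 18 interferon genes higher than in the GFP-mHP1 line. Without the GFP-dHP1 uninduced library the F test called 1789 features, 1513 of them among the 3389, and Csrnp3 was lost (adjusted p = 0.127). Without a gene filter Csrnp3 (0.0917), Oas1g (0.0748) and Iigp1 (0.138) were lost. Without the GFP-Swi6 induced library it called 10677, with Stxbp2 (0.185), U90926 (0.175), Rgs16 (0.0853), Oas1g (0.355) and Iigp1 (0.299) lost. C4b, at 0.0499 as tested, ranged from 0.0507 to 0.274 under the alternatives that ended its call.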

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

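Of the tests in this part, the share of GFP-dHP1 RNA in the GFP-Swi6 induced library was set out beforehand, and the others were chosen only after the result was seen, as was the rule that took up lists with at least 50% of members past the threshold.

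The effect of induction differed in the GFP-Swi6 line from the mean of the other lines in 798 features by edgeR. The named genes were Igf2 (log2 7.30), Dio2 (6.75), C4b (6.24), Cyp2d22 (5.41), Spats2l (5.40), Unc5c (-3.25), Calcrl (-2.86), Neil3 (-2.76), Ank1 (-2.73) and Mbnl3 (-2.73). Adjusted over the list alone, the GFP-Swi6 response was lower in 34 cell cycle genes, 51 histone genes and 18 cholesterol synthesis genes and higher in 3 adipocyte markers, and the GFP-dHP1 response was lower in 27 interferon genes.

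The interferon genes were higher after induction in the GFP-mHP1 and GFP-Swi6 lines and not in the GFP-dHP1 line. Leukocyte RNA is argued against in the GFP-mHP1 line by 7 leukocyte transcripts, whose summed CPM went from 4.25 to 2.69, a ratio of 0.632 (exact interval 0.493 to 0.809). In the GFP-Swi6 line it stays open, as the sum went from 3.34 to 5.88 CPM, a ratio of 1.76 (1.42 to 2.19). A ceiling in the GFP-dHP1 line stays open too, because 0 of 36 members had room to rise and their uninduced CPM there was a median of 3.09 times the higher induced CPM of the other lines. The GFP-dHP1 median log2 fold of -0.16 therefore does not decide on doxycycline acting alike in all lines, which stays open with an effect of the HP1 homolog, since no line had a control with doxycycline alone. The induced cells were GFP-positive in cell sorting. Selection by sorting thus goes with induction in every line and cannot be told apart from either. A response to doxycycline or sorting that differs between the lines was not tested. Each HP1 homolog came with its own line, so its effect cannot be told apart from other differences between the lines.

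Cell cycle and histone genes were lower in the GFP-Swi6 induced library. RNA of the GFP-dHP1 line, where these genes were low, would need a share of at least 68.0% for the cell cycle fall. That is the share if this RNA held no cell cycle transcripts, and it held some. The upper quartile of the share of 55 genes marking that line was 8.003%. A library of another line under this label is argued against by 33 genes marking the GFP-Swi6 line, with a median log2 ratio of 6.73 over the highest of the other lines. Doxycycline acting alike in all lines is argued against for cell cycle genes by the GFP-mHP1 line, where they were as high before induction. Their median log2 fold there was -0.28 (SD over genes 0.39), above -0.82, which is 0.5 of the GFP-Swi6 value. That bound was set after these values were seen. Each group was 1 library and the SD over genes does not measure spread between libraries, so this holds for these libraries only. For histones, at -0.99 in the GFP-mHP1 line against -1.09 for the same bound, doxycycline acting alike stays open. Slower growth for another reason, selection by cell sorting and an effect of Swi6 itself were not tested. Nor was a response to doxycycline or sorting that differs between the lines.

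Genes of the GFP-mHP1 line were seen at a low level in the GFP-dHP1 uninduced library and lower in its induced library. A mixture of RNA or cells from the GFP-mHP1 line stays open: 4 marker genes had a median share of 6.76%, with 25% of them far below it, too few to decide. With the GFP-mHP1 induced library as the source, 29 genes at least 32-fold apart had a median share of 5.99% (quartiles 4.99% and 8.61%) and 0% of them far below it, as at 16-fold and 64-fold, with 2 genes without a symbol at 93.4% and 149%, and an SD of the log2 share of 1.21, against 1.49 with the uninduced library. With 14 genes at 64-fold the SDs were 1.37 and 1.84, within the ratio of 0.75 set for this source, and with 57 genes at 16-fold 0.944 and 1.16, outside it, so the sources cannot be told apart on a choice of threshold made after the result was seen. In the reverse direction, for genes near 0 in the GFP-dHP1 uninduced library, 27 genes at 16-fold had an SD of 2.35 in the induced one. Regulation of these genes in the GFP-dHP1 line stays open as well. With the share of 5.99% subtracted the interferon median of that line was -0.21. The genes at least 2-fold apart there then numbered 563 (382 higher and 181 lower), against 455.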

How the results depend on the processing

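Protein-coding genes alone, edgeR without robust estimation, fits of the lines without 1 library, and the removal of GFP-mHP1 markers or of a GFP-mHP1 share were chosen after seeing the data. The causes of the differences below were not tested.

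Features called for induction numbered 37 with DESeq2, 3 without a gene filter and 0 to 68 with 1 line left out, against 0. Without the GFP-mHP1, GFP-dHP1 and GFP-Swi6 lines Cbx3 ranged from -0.29 to 0.015 and Cbx5 from -0.43 to 0.15, both reversed without the GFP-Swi6 line. The test of the lines called 6014 features with DESeq2, 1778 with a stricter filter, 2126 among protein-coding genes, 1789 without the GFP-dHP1 uninduced library and 10677 without the GFP-Swi6 induced library, against 3389. The response of GFP-mHP1 gave 7 with DESeq2 and 8 without a filter, against 0. That of GFP-dHP1 gave 65 with DESeq2, 20 with RLE normalization, 126 without a filter and 8 among protein-coding genes, against 0. That of GFP-Swi6 gave 3126 without a filter, against 798, and between 561 and 1149 in the other fits.

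Genes at least 2-fold apart within the GFP-mHP1 and GFP-dHP1 lines numbered 2025 and 1023 at a minimum of 20 counts. At 200 counts they numbered 552, 110 and 2497 in the GFP-mHP1, GFP-dHP1 and GFP-Swi6 lines, and at 4-fold 179, 63 and 932. The correlation of the GFP-Swi6 and GFP-mHP1 folds was 0.214 at a mean CPM of at least 1 and 0.226 by rank, and that of GFP-Swi6 and GFP-dHP1 -0.225 with the GFP-mHP1 share subtracted.

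Lists past the threshold numbered 0 with camera at an estimated correlation, 0 with fry and 5 to 14 with 1 line left out, against 13. Without the replicate block, which pairs the libraries of a line, induction gave 0 features and 13 lists passed. Germline genes (0.0490) and small nucleolar RNAs (0.0490) were then gained and mitochondrially encoded mRNAs (0.0672) and endothelial markers (0.0577) lost, and the block changed no other list call. Of the values for named genes, 668 kept their result, 32 passed only in the alternative, 28 passed only as first tested and 2 reversed. A kept result meant the same side of the threshold, with direction checked except in the test of the lines. For folds within a line it meant the same direction and a value inside the counting interval.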

Other observations

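The tests of other splits, of genes shared by the lines and of the region around Mdm2 were set out beforehand, and only the weighing of the spread of the neighbours of Mdm2 was chosen after the result was seen.

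Of the 10 splits of the 6 libraries into equal groups, 10 gave at least as many features for induction as the real one, which gave 0, and the highest other gave 1341. That count came from splits that parted the GFP-Swi6 pair alone, a structure of the samples. The splits are too few for a share under 0.05. Among splits that parted every pair, the real one had 1354 features at an unadjusted p below 0.05 and the others between 350 and 1078.

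Of 17089 genes, 19 were at least 2-fold apart in the same direction in all 3 lines (15 higher and 4 lower), against 1, 6 and 17 with the uninduced and induced libraries of 1 line exchanged. The real count lies close to the highest of these.

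Mdm2 stood at 11300 and 16146 CPM in the GFP-mHP1 line, 5198 and 5415 CPM in the GFP-dHP1 line and 12493 and 12118 CPM in the GFP-Swi6 line. A copy number difference of the region stays open. Its 10 neighbours had a median log2 difference between the GFP-mHP1 line and the others of 0.16, against 0.74 for Mdm2. That median lies below the bound set beforehand for a verdict against a copy number difference. The neighbours ranged too widely to decide, from -3.75 for Lyz2 to 0.94 for Slc35e3 and 1.38 for Gm47958. Mdm2 was low in the GFP-dHP1 line rather than high in the GFP-mHP1 line alone. So was its neighbour Slc35e3, at 4514 and 5983 CPM in the GFP-mHP1 line, 1672 and 1400 CPM in the GFP-dHP1 line and 5010 and 4567 CPM in the GFP-Swi6 line. The test of the neighbours set the GFP-mHP1 line against the mean of the others, so it cannot decide on the GFP-dHP1 line.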
